A study of Danio rerio with 12 samples.

How the data were processed

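The libraries were made by an adapted CEL-seq protocol, which primes on the poly(A) tail and counts transcript ends, from 2500 to 4800 sorted cells each, pooled after barcoding. Larval trunks with the lesion, or the same region of uninjured larvae, were dissociated and GFP-positive cells were sorted into TRIzol. The values deposited by the authors are raw counts of reads per gene with no normalization, in 1 table of 31351 entries by 12 libraries. The processing notes name BWA, genome build GRCz11 and DESeq2 1.38; what each was used for, and whether molecular identifiers were collapsed, is not given in the sources used here. The table holds 88 ERCC spike-in entries, an entry for the EGFP transgene, and 5877 entries that join overlapping genes, which were kept as they are. Chromosome positions of the genes are not given in the sources used here, and genes are named by the symbols in the table. For example, mpx is ENSDARG00000019521, il11b is ENSDARG00000058557, illr4 is ENSDARG00000008075 and col9a1b is ENSDARG00000031483.

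All 12 libraries were used, in 4 groups of 3 as the labels give them. Counts of the 31263 zebrafish and EGFP entries were analysed in R 4.3.3 with edgeR 4.0.16. Entries were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 8453, of which 77 were joint entries. Libraries were scaled by TMM factors, and a quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all libraries, with a common biological coefficient of variation of 0.380. The 5 contrasts were injury in DMSO, injury in AMD3100, AMD3100 in injured, AMD3100 in uninjured, and the interaction. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 by the quasi-likelihood F test. Standard errors (SE) of log2 fold changes were derived from that F statistic. CPM beside fold changes are scaled by TMM factors, and CPM of EGFP, rock1 and mylz3 are not.

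From knowledge of neutrophils, regeneration and the other cells a trunk sort could hold, 33 gene lists with 1293 genes were written, of which 1235 were found in the table. The 30 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided, adjusted over 150 tests. Of these, 33 had an adjusted p under 0.05; with a correlation estimated per list none did, the smallest adjusted p being 0.430. The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, gave 17. Each list was also given the count of members past the threshold over all genes and the count adjusted over the list alone. Shares of counts were compared by exact two-sided permutation tests, for which 3 against 3 libraries give a p of at least 0.1.

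The contrasts, the lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and no overlap between the groups' libraries (for 3 against 3, chance gives no overlap in 10% of genes). Where fewer than 5 passed in a direction it took the 5 smallest p. It added up to 4 members per list and 10 genes named in advance, among them the receptor and ligand genes, mpx, mmp9, il1b and lyz. Clone-based names were counted and not named. The text names part of these genes, and that part was picked when the values were known. Genes named outside the rule are said to be so.

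The alternatives were DESeq2 1.42.0 with its own size factors, RLE and upper-quartile factors, no filter, a filter of 10 CPM in 3 libraries, limma-voom, a fit to the groups of the contrast alone, the replicate number of the labels as a block, leaving out mitochondrially encoded and hemoglobin genes, thinning every library to the depth of the shallowest, an adjusted p under 0.1, and leaving out each library in turn. Chosen after the data were seen were limma-voom with sample quality weights, leaving out joint entries, leaving out the genes of the lists of other cell types, and the log2 share of the skeletal muscle list or of mitochondrial ribosomal RNA as a covariate. The pipeline was tested on simulated negative binomial counts with the depths and dispersions of these libraries and 200 changed genes. Of genes changed by 2 on the log2 scale it recovered 61.2% in the injury contrast in DMSO, 55.2% in that in AMD3100, 52.2% and 50.7% in the AMD3100 contrasts in injured and uninjured larvae, and 19.4% in the interaction. Of genes changed by 1 it recovered 7.46%, 10.4%, 7.46%, 2.99% and 1.49%. Of the calls in these simulations, 1.98%, 4.85%, 7.92%, 7.37% and 2.04% were false, in the same order.

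Totals ranged from 655451 to 12173133 counts per library, and intervals for shares of single libraries are exact Clopper-Pearson at 95%. Reads without identifiers are not independent molecules, so these intervals cover counting error only. A count of 0 allows up to 3 counts. The numbers in the sample descriptions run from 3 to 9 for all DMSO libraries and from 10 to 16 for all AMD3100 libraries, so the treatment and any order of handling that these numbers stand for cannot be told apart in the AMD3100 comparisons; they do not separate injured from uninjured libraries.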

Results

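Messenger RNA was counted in GFP-positive cells sorted from zebrafish larvae that carry mpx:GFP, a transgene driven by the promoter of the neutrophil myeloperoxidase gene. The larvae had their spinal cord transected at 3 days post-fertilization or were left uninjured, and were kept in DMSO or in 25 uM AMD3100, a small-molecule antagonist of the chemokine receptor Cxcr4, from 4 to 8 hours post-injury. AMD3100 was given with 0.1% DMSO, and the concentration of DMSO in the DMSO groups is not given in the sources used here. The 4 groups, uninjured DMSO, injured DMSO, uninjured AMD3100 and injured AMD3100, held 3 biological replicates each. Uninjured DMSO replicates 1 to 3 held 1942528, 1697395 and 6446017 counts, and injured DMSO replicates 1 to 3 held 2702372, 10553025 and 5770543. Uninjured AMD3100 replicates 1 to 3 held 2936718, 11511635 and 4387865 counts, and injured AMD3100 replicates 1 to 3 held 655451, 5730412 and 12173133.

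The sorted marker was present in every group. Its transcript EGFP reached 1737 ± 79.8 CPM (counts scaled to a common library total, mean ± SD, n = 3) in uninjured DMSO, 1452 ± 59.0 in injured DMSO, 1748 ± 180 in uninjured AMD3100 and 1084 ± 604 in injured AMD3100, where replicate 1, the shallowest library, held 397. Mitochondrial transcripts took 31.2 ± 1.12% of counts in uninjured DMSO, 22.8 ± 3.92% in injured DMSO, 19.5 ± 1.78% in uninjured AMD3100 and 19.3 ± 7.43% in injured AMD3100 (SD, n = 3). Mitochondrial ribosomal RNA alone took 7.01%, 0.768% and 17.99% in injured AMD3100 replicates 1 to 3. On the first principal component, which held 29.2% of the variance, injured AMD3100 replicate 1 scored 114.4 and the other libraries scored between -39.9 and 33.0.

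The first comparison asked what a spinal lesion changes in neutrophils of larvae without the inhibitor. In DMSO, 439 of 8453 tested genes changed with injury, 242 higher and 197 lower. The balance turned with DESeq2 (328 higher and 395 lower), RLE factors (215 and 219), upper-quartile factors (212 and 231), no filter (337 and 364), quality weights (446 and 505) and an adjusted p under 0.1 (379 and 381). The receptor gene illr4, which encodes a lectin-like immune receptor, rose from 55.2 ± 11.7 to 674 ± 144 CPM (mean ± SD, n = 3; log2 fold change 3.62, SE 0.353, adjusted p = 3.13e-04). The gelatinase gene mmp9, which degrades extracellular matrix, rose from 877 ± 157 to 2674 ± 471 CPM (log2 fold change 1.61, SE 0.344, adjusted p = 0.0144). The peroxidase gene mpx, a granule component whose promoter marks the sorted cells, fell from 3355 ± 762 to 1355 ± 359 CPM (log2 fold change -1.31, SE 0.313, adjusted p = 0.0250).

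Among the genes with the largest rises in DMSO were plekhf1, which encodes an endosomal phosphoinositide-binding protein (log2 fold change 3.97, adjusted p = 5.04e-04), tlr5b, a flagellin receptor (3.88, adjusted p = 0.00423), and aif1l, an actin-binding protein (3.71, adjusted p = 0.00195). Others were cd22, a sialic acid-binding lectin (3.24, adjusted p = 9.45e-04), and fn1b, which encodes the matrix protein fibronectin (5.36, adjusted p = 0.00384). In each of these 5 genes and in illr4, all 3 injured libraries lay above all 3 uninjured ones, as the naming rule required. The 6 largest falls among genes that met the naming rule were of muscle and embryonic globin genes: myl13 (-6.37, adjusted p = 0.0230), hbbe1.2 (-4.99, adjusted p = 0.0195), myl10 (-4.97, adjusted p = 0.0414), pvalb4 (-4.56, adjusted p = 0.0405), hbbe1.3 (-4.20, adjusted p = 0.0396) and tpm2 (-4.05, adjusted p = 0.0190). All 6 calls were lost without injured DMSO replicates 2 or 3, and some without injured DMSO replicate 1, uninjured DMSO replicates 2 or 3 or uninjured AMD3100 replicates 2 or 3 (adjusted p = 0.0507 to 0.266). The next falls included ved, a homeobox repressor (-3.77, adjusted p = 0.00158), and ryr3, an intracellular calcium release channel (-3.09, adjusted p = 0.00363). Of the 439 genes, 421 changed at least 2-fold, 64 carry clone-based names and 3 belong to joint entries of overlapping genes.

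Functional groups fixed in advance moved as follows in DMSO. The NADPH oxidase, which makes the neutrophil's superoxide, had 2 of 6 tested members higher and 0 lower (3 and 0 adjusted over the list alone), including cybb, its catalytic subunit, which went from 265 ± 22.5 to 715 ± 38.8 CPM (log2 fold change 1.43, adjusted p = 0.00384). The list had a median log2 fold change of 0.69 (adjusted p = 0.00234, and adjusted p = 0.452 with an estimated correlation). NF-kB signalling had 3 of 19 members higher and 0 lower (5 and 0 adjusted over the list alone). Their median was 0.64 (adjusted p = 0.00268, and adjusted p = 0.430 with an estimated correlation). Its member birc2, a ubiquitin ligase of the pathway that limits cell death, rose by 1.54 (adjusted p = 0.00195). Chemotaxis genes had 4 of 21 higher and 0 lower (9 and 2 adjusted over the list alone). Their median log2 fold change was 0.55 (adjusted p = 0.0156, and adjusted p = 0.430 with an estimated correlation). The Src-family kinase hck was among them (log2 fold change 1.69, adjusted p = 0.00710). Actin and motility genes had 3 of 41 higher and 0 lower (3 and 0 adjusted over the list alone), including the small GTPase rhogb (1.62, adjusted p = 0.00398). Their median was 0.26 (adjusted p = 0.0349, and adjusted p = 0.497 with an estimated correlation). Extracellular proteases and matrix genes had 3 of 15 higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.0262, and adjusted p = 0.497 with an estimated correlation).

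Further lists covered metabolism and the lysosome. Glycolysis and hypoxia genes had 9 of 31 members higher and 0 lower (12 and 1 adjusted over the list alone), and a median of 0.57 (adjusted p = 4.59e-05, and adjusted p = 0.430 with an estimated correlation). Lactate dehydrogenase ldha went from 83.2 ± 26.7 to 322 ± 33.99 CPM (log2 fold change 1.94, adjusted p = 0.00177) and the aldolase aldocb from 91.1 ± 5.50 to 351 ± 22.5 CPM (1.94, adjusted p = 0.00246). The glycolytic enzymes gapdhs (1.56, adjusted p = 0.00327) and pgam1a (1.49, adjusted p = 0.00350) also rose. Nuclear-encoded oxidative phosphorylation genes had 3 of 68 higher and 0 lower (3 and 0 adjusted over the list alone). Of the 68, 66 had a positive log2 fold change, with a median of 0.40 (adjusted p = 7.21e-07, and adjusted p = 0.497 with an estimated correlation). Lysosome and phagocytosis genes had 9 of 42 higher and 1 lower (12 and 2 adjusted over the list alone). The median of this list was 0.48 (adjusted p = 0.00161, and adjusted p = 0.497 with an estimated correlation). Examples were the proton pump subunit atp6v1e1b (2.39, adjusted p = 0.00340) and the cathepsin protease ctsc (1.64, adjusted p = 0.00509).

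Cell cycle genes had 5 of 52 members lower and 1 higher in injured DMSO (8 and 1 adjusted over the list alone). The median of the list was -0.64 (adjusted p = 9.87e-06, and adjusted p = 0.497 with an estimated correlation). The list's share of counts was 0.155 ± 0.0385% in uninjured and 0.163 ± 0.0422% in injured libraries (n = 3, exact two-sided permutation p = 0.8). The microtubule-destabilizing protein stmn1a fell from 23.7 ± 4.74 to 5.21 ± 0.822 CPM (log2 fold change -2.18, adjusted p = 0.00195). Cytosolic ribosomal protein genes had 0 of 78 members past the edgeR threshold over all genes (0 adjusted over the list alone). Of the 78, 3 had a positive log2 fold change, with a median of -0.43 (adjusted p = 7.82e-08, and adjusted p = 0.452 with an estimated correlation). Of 24 neutrophil identity genes, 3 were higher and 4 lower (5 and 7 adjusted over the list alone). Their median of 0.04, which changed sign under upper-quartile scaling, gave an adjusted p of 0.659. The list took 4.33 ± 0.151% of counts in uninjured and 3.22 ± 0.454% in injured libraries, without overlap (n = 3, exact two-sided permutation p = 0.1, the smallest possible). Besides mpx, abcb9, a lysosomal peptide transporter, fell from 116 ± 23.1 to 25.6 ± 1.95 CPM (log2 fold change -2.18, adjusted p = 5.04e-04). The spermine synthase sms fell by 1.49 on the log2 scale (adjusted p = 0.00603). Among anti-inflammatory and resolution genes, 2 of 26 were higher and 0 lower (3 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.303). Their member, the arginase arg2, rose from 15.3 ± 11.3 to 132 ± 16.7 CPM (3.13, adjusted p = 0.00137). The interleukin gene il1b, an early inflammatory cytokine, did not pass the test (means of 179 and 281 CPM, log2 fold change 0.64, adjusted p = 0.160).

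Lists of other cell types went both ways in this comparison. Skin and epithelium genes had 3 of 22 higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.233). Shares of counts rose without overlap for mesenchyme, cartilage and notochord genes (0.0126% to 0.0276%) and lymphoid genes (0.0205% to 0.0355%), and fell for thrombocyte genes (0.00828% to 0.00447%; exact two-sided permutation p = 0.1 each, the smallest possible). The median log2 fold change of lymphoid genes went the other way, at -0.84 with the muscle share as a covariate (camera adjusted p = 0.627). Erythroid genes had 3 of 15 lower and 0 higher (9 and 1 adjusted over the list alone), with a median of -2.19 (adjusted p = 0.0254, and adjusted p = 0.657 with an estimated correlation). They took 0.0227 ± 0.0144% of counts in uninjured and 0.00577 ± 5.65e-04% in injured libraries. Skeletal muscle genes had 1 of 38 lower and 0 higher (0 adjusted over the list alone), with a median of -0.94 (adjusted p = 0.0402, and adjusted p = 0.809 with an estimated correlation). They took 1.16 ± 1.01% and 0.831 ± 0.570% of counts (exact two-sided permutation p = 0.8). Among the list calls in DMSO, chemotaxis was lost without injured DMSO replicate 3, actin without uninjured DMSO replicate 1 or injured DMSO replicate 3, and proteases without uninjured DMSO replicate 2. With the muscle share as a covariate, actin was lost as well (adjusted p = 0.0506). Skeletal muscle was lost without uninjured DMSO replicate 2, injured DMSO replicate 3 or injured AMD3100 replicate 1, and the other list calls held with any library left out. The injury count in DMSO fell to 204 without uninjured DMSO replicate 2, 163 without replicate 3, 240, 173 and 187 without injured DMSO replicates 1, 2 and 3, and it was 659 without injured AMD3100 replicate 1. The call for mpx was lost without uninjured DMSO replicates 2 or 3 or any injured DMSO replicate (adjusted p = 0.0612 to 0.122). That for mmp9 was lost without uninjured DMSO replicates 2 or 3 or injured DMSO replicates 1 or 3 (adjusted p = 0.0509 to 0.0722). Of 17 other settings, 16 kept the mpx call and 17 the mmp9 call. In all, 28 of 61 named calls held in every alternative and with any library left out.

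**Figure D1:**
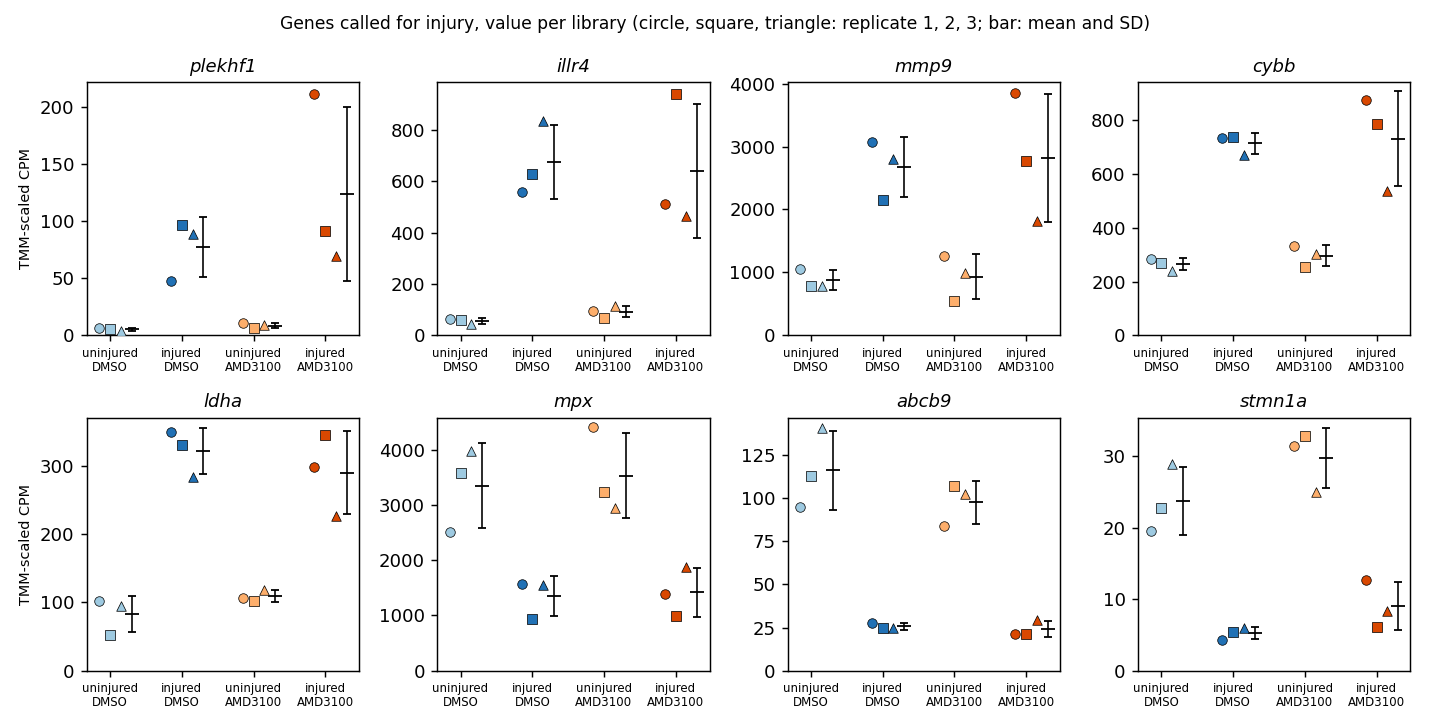
CPM scaled by TMM factors on a linear axis for 8 genes in each of the 12 libraries, in 4 groups of 3, with points for libraries and bars for group means and SD. The genes plekhf1, illr4, mmp9, cybb and ldha were higher and mpx, abcb9 and stmn1a lower in both injured groups than in the matching uninjured groups.

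The second comparison asked what the same lesion changes when Cxcr4 is inhibited. With AMD3100, 458 genes changed with injury, 254 higher and 204 lower, a balance that turned with limma-voom (314 higher and 393 lower) and in a fit of the 2 groups alone (78 and 87). The receptor genes tlr5b (log2 fold change 4.80, SE 0.687, adjusted p = 0.00164) and illr4 (2.80, SE 0.338, adjusted p = 7.90e-04) rose, illr4 from 91.8 ± 22.6 to 639 ± 262 CPM (mean ± SD, n = 3). The gelatinase gene mmp9 rose from 932 ± 363 to 2819 ± 1017 CPM (1.60, SE 0.344, adjusted p = 0.0152). The granule peroxidase gene mpx fell from 3533 ± 773 to 1422 ± 443 CPM (-1.31, SE 0.314, adjusted p = 0.0260). Among the other large rises were plekhf1, an endosomal protein (3.88, adjusted p = 7.90e-04), stoml3b, a stomatin-like membrane protein (3.73, adjusted p = 0.00114), cd22 (3.64, adjusted p = 7.90e-04) and tcnbb, a vitamin B12-binding protein (3.54, adjusted p = 0.00236). Of the 7 largest falls that met the naming rule at least 4 were of muscle genes, among them myhz1.2 (-4.19, adjusted p = 0.0425), myoz1b (-4.08, adjusted p = 0.0217), tmem38a (-3.21, adjusted p = 0.0349) and ckmb (-3.10, adjusted p = 0.0425). These 4 calls were lost without uninjured AMD3100 replicates 2 or 3 or injured AMD3100 replicate 2, and some without uninjured AMD3100 replicate 1, injured AMD3100 replicates 1 or 3, or replicates 1 or 2 of either DMSO group (adjusted p = 0.0521 to 0.145). The next falls were ctdsp2, a phosphatase that acts on RNA polymerase (-2.91, adjusted p = 7.90e-04), cbx7a, a Polycomb component (-2.73, adjusted p = 7.90e-04), and ved (-2.90, adjusted p = 0.00747). Of the 458 genes, 440 changed at least 2-fold and 62 carry clone-based names, and 4 belong to joint entries.

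The functional groups moved as follows with AMD3100. The NADPH oxidase, actin, protease and erythroid lists, called in DMSO, were not called by camera here. The interaction called none of them without a covariate. Shares of counts rose for oxidase (0.110% to 0.198%) and protease genes (0.431% to 0.906%, exact two-sided permutation p = 0.1 each). They were 15.0% and 14.75% for actin (exact p = 0.9) and 0.0127% and 0.0166% for erythroid genes (exact p = 0.7). Lysosome and phagocytosis genes had 12 of 42 higher and 2 lower (15 and 2 adjusted over the list alone). The median was 0.65 (adjusted p = 7.21e-07, and adjusted p = 0.452 with an estimated correlation). The proton pump subunit atp6v0ca rose from 317 ± 106 to 1303 ± 420 CPM (log2 fold change 2.04, adjusted p = 0.00320), and the cathepsin ctsla rose by 2.24 on the log2 scale (adjusted p = 0.00332). NF-kB signalling had 3 of 19 higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.56 (adjusted p = 0.00640, and adjusted p = 0.430 with an estimated correlation). The ligase gene birc2 rose by 1.40 on the log2 scale (adjusted p = 0.00352). Glycolysis and hypoxia genes had 8 of 31 higher and 2 lower (12 and 3 adjusted over the list alone). The median was 0.28 (adjusted p = 0.00971, and adjusted p = 0.497 with an estimated correlation). This call was lost without injured AMD3100 replicate 2, and with the muscle share as a covariate (adjusted p = 0.0901). The aldolase aldocb rose from 123 ± 11.4 to 446 ± 205 CPM (1.85, adjusted p = 0.00335). Oxidative phosphorylation genes had 5 of 68 higher and 0 lower (14 and 0 adjusted over the list alone). Of the 68, 57 had a positive log2 fold change, with a median of 0.53 (adjusted p = 1.45e-07, and adjusted p = 0.497 with an estimated correlation).

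Cell cycle genes had 4 of 52 lower and 0 higher with injury in AMD3100 (9 and 0 adjusted over the list alone). The median was -0.69 (adjusted p = 4.77e-06, and adjusted p = 0.497 with an estimated correlation). Their share of counts was 0.168 ± 0.0150% and 0.137 ± 0.00943% (n = 3, exact two-sided permutation p = 0.1, and 0.2 with mitochondrial ribosomal RNA left out of the total). The member stmn1a fell from 29.7 ± 4.15 to 8.97 ± 3.35 CPM (log2 fold change -1.86, adjusted p = 0.00503). Ribosomal protein genes had 2 of 78 lower and 0 higher (0 adjusted over the list alone), with a median of -0.36 (adjusted p = 3.59e-04, and adjusted p = 0.497 with an estimated correlation). Blood progenitor genes had 1 of 11 lower and 0 higher (2 and 0 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.0475, and adjusted p = 0.497 with an estimated correlation). This call held in 3 of the 12 fits with 1 library left out, those without uninjured DMSO replicate 3, injured DMSO replicate 2 or injured AMD3100 replicate 1, and it was lost with the muscle share as a covariate (adjusted p = 0.249). Chemotaxis genes had 2 of 21 higher and 1 lower (5 and 2 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.233; 0.0230 by fry, which passed in 4 of 12 fits with 1 library left out). Of 24 neutrophil identity genes, 3 were higher and 6 lower (4 and 7 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.209; 0.0455 by the fry test, which passed in 0 of 12 fits with 1 library left out). Its share of counts was 5.41 ± 1.15% in uninjured and 3.49 ± 0.379% in injured libraries, without overlap (exact two-sided permutation p = 0.1). The chemoattractant-like gene lect2l, abundant in neutrophils, fell from 3167 ± 1225 to 672 ± 229 CPM (-2.23, adjusted p = 0.00335). Among anti-inflammatory and resolution genes, 3 of 26 were higher and 1 lower (4 and 3 adjusted over the list alone; median 0.10, adjusted p = 0.233), with arg2 rising by 2.86 (adjusted p = 0.00214). The cytokine gene il1b did not pass (194 ± 31.5 and 249 ± 43.5 CPM, log2 fold change 0.35, adjusted p = 0.471).

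Skeletal muscle genes moved with this comparison too: 4 of 38 were lower and 0 higher (21 and 0 adjusted over the list alone), with a median of -2.42 (adjusted p = 4.74e-13, and adjusted p = 0.497 with an estimated correlation). The list took 3.71 ± 1.83% of counts in uninjured and 0.828 ± 0.753% in injured AMD3100 libraries (n = 3, exact two-sided permutation p = 0.2). With the log2 share of that list as a covariate, added after the data were seen, the injury count with AMD3100 was 177, and 156 of the 458 genes remained past the threshold. The count was 298 without injured DMSO replicate 2, 234, 119 and 196 without uninjured AMD3100 replicates 1, 2 and 3, and 217 without injured AMD3100 replicate 2. The call for mpx was lost without any uninjured AMD3100 replicate or injured AMD3100 replicate 2 (adjusted p = 0.0536 to 0.114). That for mmp9 was lost without uninjured AMD3100 replicates 2 or 3 (adjusted p = 0.0521 to 0.0769). Of 17 other settings, 15 kept the mpx call and 15 the mmp9 call. In all, 23 of 66 named calls held in every alternative and with any library left out.

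The injury response was then compared between the treatments. Of the genes that rose with injury, 158 did so in both DMSO and AMD3100 (7.27 expected for independent calls), and of those that fell, 88 did so in both (4.75 expected). Both sets included named genes: illr4, plekhf1, tlr5b, cd22, mmp9, cybb, ldha and aldocb were higher, and mpx, abcb9, sms, stmn1a, ctdsp2, cbx7a and ved lower, in both. No gene rose in one treatment and fell in the other. Of 651 genes called in either treatment, 633 had the same sign in both. The log2 fold changes correlated across the 8453 genes with Pearson r = 0.561 and Spearman rho = 0.579 (genes are not independent replicates). The Pearson value was 0.719 for genes with at least 10 CPM in at least 3 libraries.

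**Figure D2:**
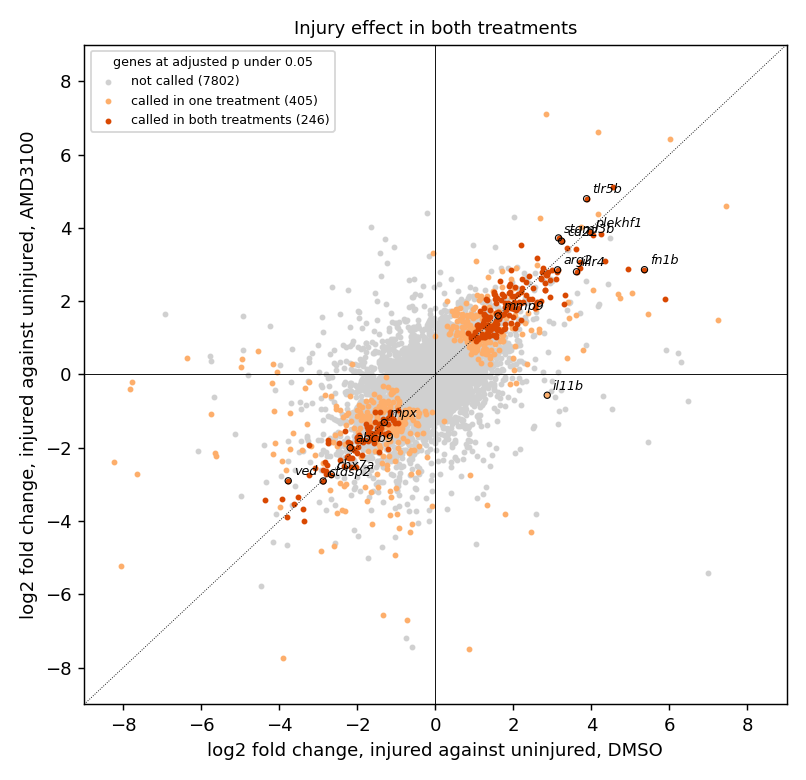
Log2 fold change of injured over uninjured in DMSO (horizontal axis) and in AMD3100 (vertical axis), 1 point per tested gene, with 651 genes called in at least 1 treatment, 246 of them in both, and 1 gene outside the axes. The 246 genes called in both lie in the quadrants where the signs match.

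Whether injury acted differently under Cxcr4 inhibition was tested directly by the interaction, and 0 genes passed with edgeR (265 at an unadjusted p under 0.05, with 423 expected by chance; 0 by DESeq2). Without the expression filter some genes passed, and their count is given with the other processing settings. For mpx the difference of the log2 fold changes was -0.00 (SE 0.436) and for mmp9 it was -0.01 (SE 0.475), each with an adjusted p of 1. The genes with the smallest p included il11b, a cytokine of the interleukin-6 family linked to tissue repair, at 5.16 ± 1.17, 38.3 ± 14.7, 10.3 ± 4.93 and 6.05 ± 7.23 CPM in uninjured DMSO, injured DMSO, uninjured AMD3100 and injured AMD3100 (difference -3.44, SE 0.970, adjusted p = 1). Its injury effect passed in DMSO (log2 fold change 2.87, adjusted p = 0.0290) and not in AMD3100 (-0.57, adjusted p = 0.690). The DMSO call was lost without any uninjured DMSO replicate or injured DMSO replicates 1 or 2 (adjusted p = 0.0750 to 0.101). Others were the muscle genes myl13 (6.83) and tpm2 (4.11), the embryonic globin hbbe1.2 (5.18), and, with negative differences, the vesicle-tethering gene vps52 (-1.47) and the splicing factor rbm17 (-2.18). None of these passed (adjusted p = 1).

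Among the fixed lists, glycolysis had 8 of 31 positive differences, with a median of -0.19 (adjusted p = 0.0448, and adjusted p = 0.497 with an estimated correlation), with 0 members past the threshold, also 0 adjusted over the list alone. This call was lost without uninjured DMSO replicates 1 or 2, injured DMSO replicate 2, uninjured AMD3100 replicates 1 or 3, or injured AMD3100 replicate 3. Skeletal muscle had 4 of 38 positive, with a median of -1.56 (adjusted p = 1.06e-10, and adjusted p = 0.497 with an estimated correlation), again with 0 members passing. Chemotaxis genes had 6 of 21 positive, with a median of -0.24 (adjusted p = 0.183; 0.0285 by fry, and 0.0691 to 0.367 with 1 library left out). Without injured AMD3100 replicate 3 the interaction count was 2, il11b (difference -5.75, adjusted p = 0.0340) and the zinc finger gene znf292b (-3.23, adjusted p = 0.0340), the latter chosen for mention after its values were seen.

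The third comparison, AMD3100 against DMSO in injured larvae, asked which neutrophil transcripts the inhibitor changes at the lesion. No gene passed the edgeR test, with 466 at an unadjusted p under 0.05 against 423 expected by chance, and DESeq2 called 1 gene, stxbp5a. More genes passed when the expression filter was dropped, as given with the other processing settings. Transcripts of mpx (log2 fold change 0.07, SE 0.308), mmp9 (0.08, SE 0.335) and il1b (-0.18, SE 0.249) had adjusted p values of 0.992 or more. The granule enzyme gene lyz, a lysozyme, stood at 2377 ± 629 CPM in injured DMSO and 5026 ± 4727 in injured AMD3100 (1.08, SE 0.496, adjusted p = 0.901), and its log2 fold change was -0.04 without injured AMD3100 replicate 1. The smallest adjusted p belonged to stxbp5a, a syntaxin-binding regulator of secretion, at 55.1 ± 18.2 and 12.3 ± 4.95 CPM (-2.11, SE 0.391, adjusted p = 0.616 with edgeR and 0.00317 with DESeq2). The next lower genes included ccnd1, the G1 cyclin D1, at 199 ± 73.3 and 71.1 ± 30.3 CPM (-1.45, adjusted p = 0.901), the kinase prkcea (-1.64) and the mitochondrial carrier slc25a44b (-1.23). The higher ones were the cathepsin ctsz at 44.9 ± 3.36 and 82.6 ± 5.78 CPM (0.87), the prenyl diphosphate synthase ggps1 (1.16), and the parvalbumin pvalb4 of muscle (4.101), with adjusted p = 0.901 each.

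As lists, 4 groups were higher and 1 lower with AMD3100 in injured larvae, each with 0 members past the edgeR threshold and 0 adjusted over the list alone. Ribosomal protein genes had 59 of 78 positive (median 0.21, adjusted p = 6.84e-04, and adjusted p = 0.497 with an estimated correlation). Lysosome and phagocytosis genes had 34 of 42 positive (0.28, adjusted p = 8.28e-04, and adjusted p = 0.497 with an estimated correlation), and oxidative phosphorylation genes 53 of 68 (0.22, adjusted p = 0.00161, and adjusted p = 0.555 with an estimated correlation). Erythroid markers had 13 of 15 positive (1.32, adjusted p = 0.0156, and adjusted p = 0.605 with an estimated correlation). Extracellular proteases and matrix genes had 2 of 15 positive (-0.39, adjusted p = 0.0146, and adjusted p = 0.497 with an estimated correlation). The ribosomal call held with any library left out. The lysosome call was lost without injured AMD3100 replicate 2, the protease call without replicate 3, and the oxidative phosphorylation call without replicate 1 or injured DMSO replicate 1. The erythroid call was lost without injured AMD3100 replicates 1 or 2 or injured DMSO replicates 1 or 3. Chemotaxis genes of the Cxcr4-Cxcl12 list had 5 of 21 positive (-0.19, adjusted p = 0.103), with 0 members past the threshold. The fry test called this list lower (adjusted p = 0.0156), a call that held only without uninjured DMSO replicate 2, injured DMSO replicate 1 or any uninjured AMD3100 replicate, and reached 0.196 otherwise.

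Without injured AMD3100 replicate 3 the count for AMD3100 in injured larvae was 72, of which 2 were higher and 70 lower, and with any other single library left out it was 0. These lower genes, chosen for mention after their values were seen, included zyx, a focal adhesion protein (log2 fold change -3.16, adjusted p = 0.00816), rock1, a kinase of actomyosin contraction (-3.33, adjusted p = 0.00943), and il11b (-4.80, adjusted p = 0.00816). The CPM of rock1 were 30.5, 32.8 and 410 in injured AMD3100 replicates 1 to 3, against a mean of 310 in injured DMSO.

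**Figure D3:**
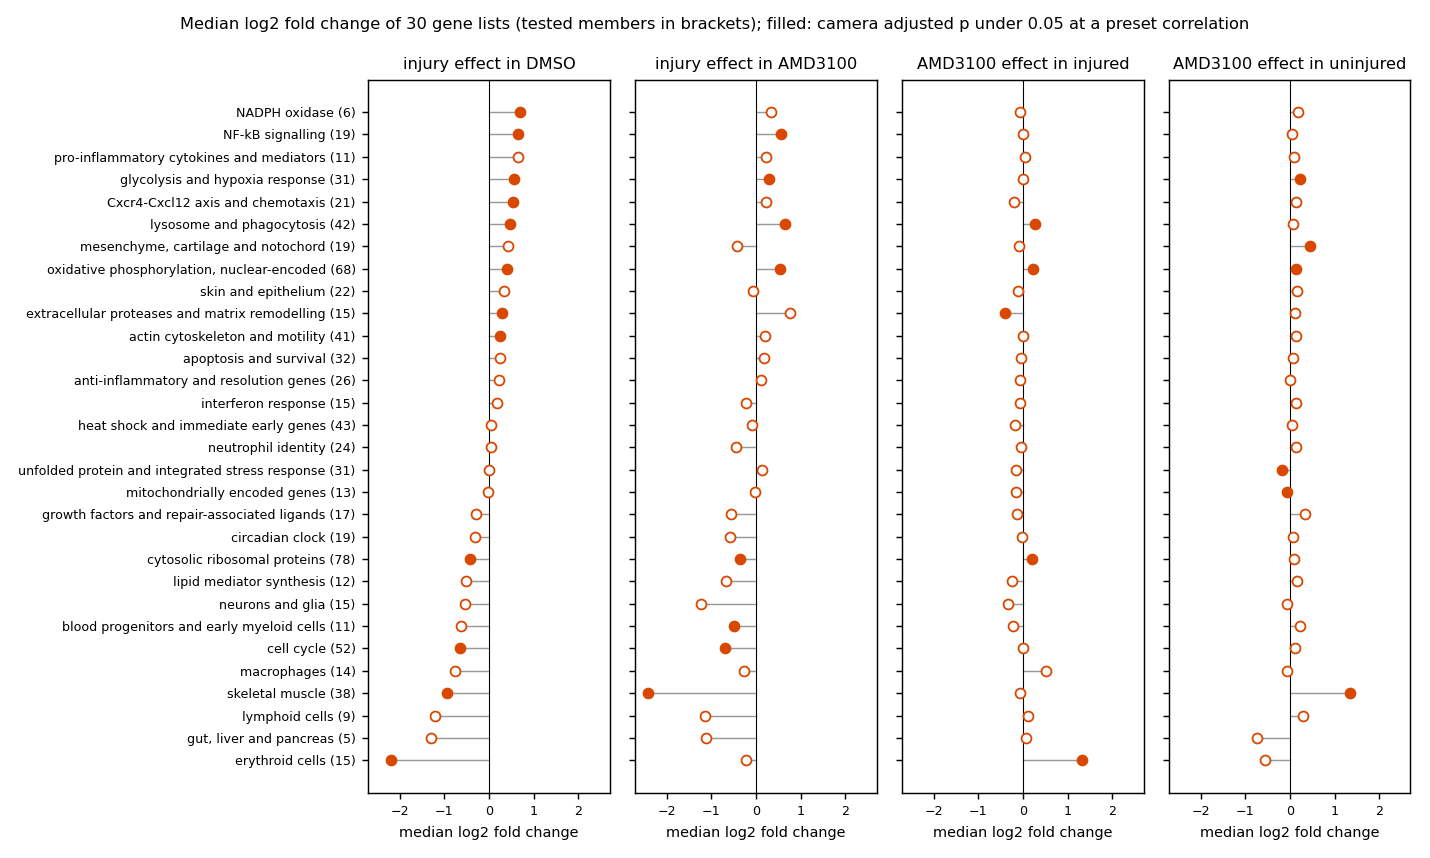
Median log2 fold change of the 30 tested gene lists (vertical axis, 1 line per list) in the injury comparisons in DMSO and AMD3100 and the AMD3100 comparisons in injured and uninjured larvae, with filled points where the camera test gave an adjusted p under 0.05. Skeletal muscle lies furthest to the right for AMD3100 in uninjured larvae, with a median of 1.34, and furthest to the left for injury with AMD3100, with a median of -2.42.

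The fourth comparison, AMD3100 against DMSO in uninjured larvae, gives the background effect of the inhibitor. The cartilage collagen gene col9a1b was the single gene to pass, at 0.787 ± 0.688 CPM in DMSO and 20.4 ± 9.30 in AMD3100 (log2 fold change 4.36, SE 0.627, adjusted p = 0.0371), with 433 genes at an unadjusted p under 0.05 against 423 expected by chance, and 19 called by DESeq2. The collagen gene col2a1a (4.37 ± 1.12 and 40.3 ± 15.6 CPM, log2 fold change 3.28, adjusted p = 0.369) and the matrix proteoglycan gene epyc (3.38, adjusted p = 0.721) did not pass. Nor did the lower genes with the smallest p, such as the kinases pak2a (-3.04, adjusted p = 0.369) and prkci (-1.45, adjusted p = 0.369). Of the genes named in advance, mpx stood at 0.07 (SE 0.308), mmp9 at 0.09 (SE 0.336), il1b at 0.11 (SE 0.249) and lyz at 0.14 (SE 0.490). Of 24 neutrophil identity genes 21 were positive, with a median of 0.13 (adjusted p = 0.303), 0 past the threshold and 0 adjusted over the list alone. The list's share was 4.21 to 4.50% of counts in the uninjured DMSO and 4.61 to 6.73% in the uninjured AMD3100 libraries (n = 3, exact two-sided permutation p = 0.1). Mitochondrial ribosomal RNA took 16.3 to 21.5% and 6.18 to 11.2% there, and with it left out of the total the list's shares overlapped, at 5.03 to 5.74% and 5.18 to 7.17% (exact p = 0.6). The call of col9a1b held in 3 of the 12 fits with 1 library left out, those without injured DMSO replicate 3, uninjured AMD3100 replicate 2 or injured AMD3100 replicate 1 (adjusted p = 0.0551 to 0.199 in the others). Without injured AMD3100 replicate 1, col2a1a passed as well (3.29, adjusted p = 0.0236).

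By list, skeletal muscle genes were higher with AMD3100 in uninjured larvae, with 35 of 38 positive and a median of 1.34 (adjusted p = 2.87e-15, and adjusted p = 0.497 with an estimated correlation), with 0 members past the threshold and 0 adjusted over the list alone. The share of counts of this list was 0.913%, 2.26% and 0.293% in uninjured DMSO replicates 1 to 3 and 1.68%, 4.21% and 5.23% in uninjured AMD3100 replicates 1 to 3 (exact two-sided permutation p = 0.2). Mesenchyme, cartilage and notochord genes had 14 of 19 positive (1 higher and 0 lower, 3 and 0 adjusted over the list alone), with a median of 0.45 (adjusted p = 8.28e-04, and adjusted p = 0.497 with an estimated correlation). Glycolysis genes had 27 of 31 positive (median 0.22, adjusted p = 0.00651, and adjusted p = 0.497 with an estimated correlation) and oxidative phosphorylation genes 58 of 68 (0.14, adjusted p = 0.0254, and adjusted p = 0.699 with an estimated correlation). Stress genes of the unfolded protein response had 9 of 31 positive (-0.18, adjusted p = 0.0173, and adjusted p = 0.548 with an estimated correlation), and mitochondrially encoded genes 2 of 13 (-0.07, adjusted p = 0.0228, and adjusted p = 0.497 with an estimated correlation). In each of these 4 lists 0 members passed, and adjusted over the list alone 1 mitochondrially encoded gene was lower and 0 were in the other 3 lists. The glycolysis and muscle calls held with any library left out, and the cartilage call was lost without uninjured DMSO replicate 3. The unfolded protein call was lost without uninjured DMSO replicates 1 or 2, the mitochondrial call without uninjured DMSO replicate 3 or uninjured AMD3100 replicate 2, and the oxidative phosphorylation call held in 5 of the 12 fits, those without uninjured DMSO replicate 3, uninjured AMD3100 replicate 1 or any injured AMD3100 replicate. With the muscle share as a covariate these 4 calls, cartilage, unfolded protein, mitochondrial and oxidative phosphorylation, were lost (adjusted p = 0.0750, 0.122, 0.0876 and 0.148).

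The effects of AMD3100 in injured and uninjured larvae correlated across genes with Pearson r = 0.135 and Spearman rho = 0.173, and 56.0% of genes had the same sign. Leaving out each library in turn gave this Pearson value a jackknife SE of 0.147, larger than the value itself. The injury effect in DMSO and the AMD3100 effect in injured larvae share the injured DMSO libraries. In 20 simulations without any effect their Pearson r was -0.459, their Spearman rho -0.437 and their covariance -0.174 (SD 0.00723). The observed values were -0.281, -0.181 and -0.209, weaker than the simulated ones in both correlations and larger in covariance. The observed Pearson value had a jackknife SE of 0.285 over left-out libraries, larger than its distance from the simulated one.

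Transcripts of the receptor and ligand themselves were scarce. The receptor gene cxcr4a had 13, 14, 11 and 24 counts in total in uninjured DMSO, injured DMSO, uninjured AMD3100 and injured AMD3100, and did not pass the expression filter. The second receptor gene cxcr4b, counted jointly with an overlapping gene, had 29, 11, 33 and 10 counts. Its mean CPM without TMM factors were 2.438, 0.9898, 2.459 and 2.229 in the same order. In injured AMD3100, replicate 1 held 6.103 CPM from 4 counts. It passed the expression filter, and neither the AMD3100 comparisons nor the interaction called it. The ligand gene cxcl12a had 0, 13, 4 and 48 counts, and 43 of the 48 came from injured AMD3100 replicate 3. The cytokine gene tnfa had 0, 5, 0 and 10 counts. The anti-inflammatory cytokine il10 had 4, 40, 3 and 30 counts (log2 fold change with injury 2.28 in DMSO, adjusted p = 0.232, and 2.77 in AMD3100, adjusted p = 0.157). The transforming growth factor gene tgfb1a had 40, 35, 28 and 22 counts. As the groups differ in depth, its mean CPM without TMM factors were 5.074, 2.115, 1.337 and 0.6948 in the same order. The genes cxcl12a and tnfa also did not pass the expression filter, and were not tested.

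**Figure D4:**
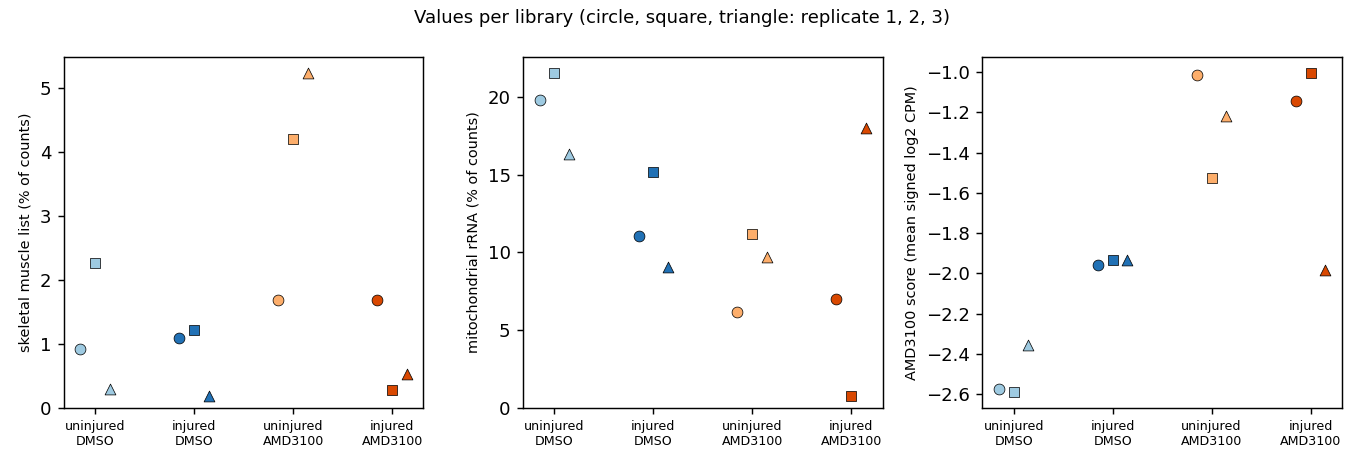
Skeletal muscle share of counts (percent), mitochondrial ribosomal RNA share of counts (percent) and AMD3100 score (mean log2 CPM over 468 genes, signed by their change in uninjured larvae) in each of the 12 libraries by group. Injured AMD3100 replicate 3 has a score of -1.99, below the 3 injured DMSO libraries at -1.96 to -1.93, and replicates 1 and 2 score -1.15 and -1.005. With libraries thinned to equal depth, replicate 3 scores -1.93, within their range of -1.98 to -1.90.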

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

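Of the tests in this part, those of RNA from other tissues, of the muscle share and the mitochondrial ribosomal RNA share as covariates, of counts expected at the uninjured level, of depth in genes not tested after thinning, and of the most abundant genes under scaling by totals were chosen after the result was seen. The genes il11b, rock1, zyx and znf292b without injured AMD3100 replicate 3 were also examined only then.

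The interaction test called 2 gene lists, with an adjusted p of 0.0448 for glycolysis and hypoxia genes and 1.06e-10 for skeletal muscle genes, and neither call was kept with an estimated correlation (adjusted p = 0.497 for each). The glycolysis call held in 6 of 12 fits with 1 library left out, and the muscle list reversed with its own share as a covariate. ERCC spike-ins, which no comparison used, took a share of counts whose lower bound lay above 0.0120%, the highest upper bound in uninjured DMSO, in 5 libraries (these bounds cover counting error only). The shares were 0.0159% in injured DMSO replicate 1 (exact Clopper-Pearson interval 0.0144 to 0.0175%), 0.0133% in replicate 2 (0.0126 to 0.0140%), 0.0131% in uninjured AMD3100 replicate 3 (0.0120 to 0.0142%), 0.0436% in injured AMD3100 replicate 1 (0.0387 to 0.0490%) and 0.0129% in injured AMD3100 replicate 3 (0.0123 to 0.0135%).

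In uninjured larvae with AMD3100 the skeletal muscle and cartilage lists were called higher with 0 of 38 and 1 of 19 genes past the threshold, and neither call was kept with an estimated correlation (adjusted p = 0.497 each), nor the cartilage call with the muscle covariate (adjusted p = 0.0750). RNA or cells of other tissues in the sorted samples cannot be told apart from a change in gene expression. All 10 of the most abundant muscle genes were higher (median log2 fold change 1.43, none past the gene-level threshold). One of them, the myosin light chain gene mylz3, stood at 5847 CPM in uninjured DMSO and 20310 in uninjured AMD3100. But this restates the list's own result, in which 35 of 38 tested genes were positive. A difference in depth stays open: the list's median log2 fold change was 1.33 after thinning and 1.34 before. Random thinning of reads keeps each gene's expected share of counts, so it could hardly move this median. The glycolysis list, called there with 0 of 31 genes past the threshold and not with an estimated correlation (adjusted p = 0.497), is not accounted for by the muscle share, since its median log2 fold change was 0.348 with that share as a covariate and 0.217 without it. An effect of AMD3100 on these tissues was not tested and stays open, as does the order of the description numbers, which cannot be told apart from the drug.

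Without injured AMD3100 replicate 3, 72 genes were called for AMD3100 in injured larvae, 70 of them lower, il11b among them. The 70 genes had a median of 28.1 counts expected in replicate 1 at the level of the uninjured libraries, which were in neither group. But genes had to be well counted to be called lower, and reads may not be independent molecules. Chance in counting few reads in replicate 1 therefore stays open. The 33.1 counts expected at the injured DMSO level decide nothing on depth, because the genes were picked for a difference from that level, so a loss of molecules before counting stays open. A DMSO library under a wrong label as replicate 3 and a library in which the drug left no difference cannot be told apart by the AMD3100 score. It used 468 genes at an unadjusted p under 0.05 between the uninjured groups (343 expected by chance, 0 past the threshold). The score is not specific to the drug: uninjured DMSO libraries scored -2.59 to -2.35 and injured DMSO libraries -1.96 to -1.93. Replicate 3 scored -1.99, -3.30 SD from the highest injured DMSO score, an SD of 3 close values. Thinned to equal depth, it scored -1.93, inside their range of -1.98 to -1.90. Replicates 1 and 2 scored -1.15 and -1.005 without thinning. In log2 CPM over the tested genes, replicate 3 correlated at 0.940, 0.963 and 0.958 with injured DMSO replicates 1 to 3. With injured AMD3100 replicates 1 and 2 it correlated at 0.843 and 0.930. Either a wrong label or an absent drug difference could give such values. Mitochondrial ribosomal RNA also set the replicates apart, at 7.01%, 0.768% and 17.99% of counts, so RNA quality stays open as well.

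The injury response of 439 genes in DMSO and 458 in AMD3100 was weighed against 4 technical sources. A few abundant genes shifting the scaling stay open for the balance in DMSO, which turned under RLE and upper-quartile factors. A fit without the 21 genes among the 10 most abundant of any library, scaled by totals alone, called 429 genes in DMSO (256 higher, 173 lower). In AMD3100 it called 455 (293 and 162). All 894 calls compared (100%) kept their sign and at least 50% of their log2 fold change. Calls this large (median absolute log2 fold change 1.78 in DMSO, 1.74 in AMD3100) could hardly fail that criterion. The 443 genes called in DMSO without mitochondrially encoded and hemoglobin genes decide nothing, because TMM scaling trims such genes already. Muscle RNA in the uninjured samples is argued against as the whole source in AMD3100 only. With the muscle share as a covariate, 98.4% of 897 calls kept their sign and at least 50% of their log2 fold change. In DMSO that share differed little (1.16% and 0.831%, exact two-sided permutation p = 0.8), so the covariate could hardly move the calls. In AMD3100, where it was 3.71% and 0.828%, 96.9% of the 458 calls did so. The AMD3100 calls fell to 177 with that covariate, and 156 of the 458 genes remained past the threshold. The median SE there went from 0.357 to 0.450, while the median absolute log2 fold change was 1.74 with and without it. Mitochondrial ribosomal RNA took 19.2% of counts in uninjured and 11.8% in injured DMSO, without overlap. As the whole source it is argued against there. With its share as a covariate, 100% of the 439 calls in DMSO kept their sign and at least 50% of their log2 fold change. Of these, 335 remained past the threshold, and the median absolute log2 fold change went from 1.78 to 1.74 (SE 0.360 to 0.366). In AMD3100 the mean shares were 9.01% and 8.59%, too close for the covariate to decide. There 100% of the 458 calls met the same criterion and 271 remained past the threshold, with the median going from 1.74 to 1.64 (SE 0.357 to 0.373). Depth stays open. Of the 707 calls still tested after thinning, 99.6% kept their sign and at least 50% of their log2 fold change. Random thinning keeps each gene's expected share of counts, so this could hardly fail. Of the other 190 calls 95.3% did so, at a median of 5.33 counts in the higher group, too near the floor to decide. RNA quality that the marker does not follow was not tested. A response of neutrophils to the lesion stays as a hypothesis, found and tested on the same libraries.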

How the results depend on the processing

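Chosen after the data were seen were the fits with sample quality weights, without joint entries, without the lists of other cell types, and with the muscle share or the mitochondrial ribosomal RNA share as a covariate.

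Injury effects kept their sign for all named genes in every fit. Most of these genes were named because they passed, so a change of sign was unlikely. The other settings include the main fit at an adjusted p under 0.1, which cannot lose a call. Some left-out libraries lay outside the groups of the contrast. Over the other settings, calls of named genes were kept 974 times and lost 46 times in DMSO, and 993 and 117 times in AMD3100. With 1 library left out they were kept 591 and lost 141 times in DMSO, and 627 and 165 times in AMD3100. With the replicate number as a block over all groups, the counts were 353 for injury in DMSO, 325 for injury in AMD3100, 0 and 1 for AMD3100 in injured and uninjured larvae, and 0 for the interaction. Same-number libraries of different groups correlated at -0.111 to 0.140 beyond their groups over 18 pairs (mean 0.003), and 7 of 12 libraries correlated best with their own number. Between injured and uninjured libraries, same-number pairs correlated at 0.0423, 0.0475 and 0.140 in DMSO and at 0.0596, -0.0806 and 0.0507 in AMD3100. Whether the numbers pair libraries within a treatment is therefore not decided. Depth limits what can be seen: after thinning to the shallowest library, the counts were 240 for injury in DMSO and 0 for AMD3100 in uninjured larvae. Except where the construction shows it (fewer libraries, fewer counts, a looser threshold), the cause was not tested.

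For injury in DMSO (439), DESeq2 gave 723, no filter 701, the 2 groups alone 722, a block within treatment 277, an adjusted p under 0.1 gave 760 and quality weights 951. For injury in AMD3100 (458), DESeq2 gave 731, no filter 714, limma-voom 707, the 2 groups alone 165, a block within treatment 284, an adjusted p under 0.1 gave 735, the muscle covariate 177 and the ribosomal RNA covariate 281. For AMD3100 in injured larvae (0), DESeq2 gave 1 and no filter 105; in uninjured larvae (1), DESeq2 gave 19, no filter 145, the muscle covariate 2, and limma-voom, quality weights, the ribosomal RNA covariate, the 2 groups alone and leaving out the lists of other cell types 0. For the interaction (0), no filter gave 68. Of 33 list calls, 0 remained with an estimated correlation and 12 by fry, which made 17 calls in all. With the muscle covariate, 23 remained, 8 were lost and 2 reversed, and 3 were gained: neutrophil identity lower for injury in AMD3100 (adjusted p = 0.0492) and in the interaction (adjusted p = 0.0322), and erythroid genes higher in the interaction (adjusted p = 0.00127). The Pearson similarity of the injury effects (0.561) was 0.719 with the stricter filter.

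Leaving out 1 library gave 163 to 659 for injury in DMSO, 119 to 574 for injury in AMD3100, 0 to 72 for AMD3100 in injured and 0 to 2 in uninjured larvae, 0 to 2 for the interaction, and 28 to 36 list calls. The Pearson values ranged from 0.439 to 0.520 for the injury effects, 0.0551 to 0.216 for the AMD3100 effects and -0.468 to -0.0941 for the pair that shares libraries.

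Some signs reversed. With the ribosomal RNA covariate, mmp9 was -0.0841 for AMD3100 in injured and -0.0619 in uninjured larvae. For AMD3100 in uninjured larvae, mmp9 was -0.12 with quality weights and lyz -0.0792 with the muscle covariate. The interaction of mpx was 0.0599 with DESeq2, 0.0598 with RLE and 0.0634 with upper-quartile factors, 0.0444 with the stricter filter, 0.00954 without mitochondrial and hemoglobin genes, and 0.16 with quality weights. The interaction of mmp9 was 0.0716 with DESeq2, 0.0717 with RLE and 0.0711 with upper-quartile factors, 0.0600 with the stricter filter, 0.0645 after thinning, 0.00298 with limma-voom, 0.00855 with the replicate block, 0.00843 with the block within treatment, 0.00637 without mitochondrial and hemoglobin genes, 0.14 with quality weights and 8.07e-04 with the muscle covariate. The muscle list, from which that covariate was built, reversed with it, from a median of 1.34 to -0.41 for AMD3100 in uninjured larvae (adjusted p = 0.0322) and from -1.56 to 0.52 for the interaction (adjusted p = 0.0385). With 1 library left out, AMD3100 in injured larvae gave -0.15 to 0.28 for mpx, -0.25 to 0.00242 for il1b, -0.21 to 0.34 for mmp9 and -0.0424 to 1.45 for lyz, which was 1.08 with all libraries. In uninjured larvae the ranges were -0.15 to 0.20, -0.0298 to 0.27, -0.22 to 0.36 and -0.0831 to 0.32 in the same order. For the interaction they were -0.19 to 0.24 for mpx, -0.30 to 0.31 for mmp9 and -0.19 to 1.34 for lyz.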

Other observations

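Nothing in this part was chosen after the result was seen, apart from the selection of genes shown.

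Further gene groups held single genes that changed with injury in both treatments. Heat shock and immediate early genes had 3 of 43 higher and 0 lower in DMSO (4 and 1 adjusted over the list alone; median 0.05, changing sign under upper-quartile scaling; adjusted p = 0.514) and 4 higher and 2 lower in AMD3100 (4 and 5 adjusted over the list alone; median -0.09; adjusted p = 0.851). The inducible chaperone gene hsp90aa1.2 rose from 18.01 ± 8.66 to 93.3 ± 9.33 CPM in DMSO (SD, n = 3; log2 fold change 2.41, adjusted p = 0.00133) and by 2.68 in AMD3100 (adjusted p = 9.67e-04). Among growth factors and repair-associated ligands, 3 of 17 were higher and 0 lower in DMSO (3 and 0 adjusted over the list alone; median -0.28, adjusted p = 0.927) and 2 higher and 0 lower in AMD3100 (2 and 0 adjusted over the list alone; median -0.57, adjusted p = 0.922). The galectin gene lgals9l1 rose from 13.3 ± 7.95 to 92.2 ± 18.4 CPM in DMSO (2.80, adjusted p = 0.00195) and from 21.1 ± 7.06 to 122 ± 48.1 CPM in AMD3100 (2.51, adjusted p = 0.00295). In lipid mediator synthesis, 3 of 12 were higher and 2 lower in DMSO (3 and 2 adjusted over the list alone; median -0.50, adjusted p = 0.625) and 2 higher and 1 lower in AMD3100 (3 and 4 adjusted over the list alone; median -0.67, adjusted p = 0.303); hpgd, which inactivates prostaglandins, fell from 264 ± 10.4 to 60.3 ± 20.7 CPM in AMD3100 (-2.12, adjusted p = 0.00335). Apoptosis and survival genes had 3 of 32 higher and 0 lower in DMSO (5 and 1 adjusted over the list alone; adjusted p = 0.194) and 2 higher and 0 lower in AMD3100 (2 and 0 adjusted over the list alone; adjusted p = 0.267).

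Macrophage markers had 2 of 14 lower and 0 higher in DMSO (6 and 2 adjusted over the list alone; median -0.76, adjusted p = 0.303) and 2 lower and 1 higher in AMD3100 (5 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.777). The secreted galectin-3-binding protein gene lgals3bpb fell in both, from 12.6 ± 3.81 to 1.34 ± 0.0676 CPM in DMSO (-3.23, adjusted p = 0.00230) and from 15.5 ± 5.93 to 1.75 ± 1.55 CPM in AMD3100 (-2.74, adjusted p = 0.00511). The macrophage list's share of counts went the other way, from 0.0192 ± 0.00670% to 0.0453 ± 0.0105% in DMSO (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible) and from 0.0200 ± 0.00443% to 0.0483 ± 0.0291% in AMD3100 (exact p = 0.3). Neuron and glia markers had 0 of 15 members past the edgeR threshold in either injury comparison (adjusted over the list alone, 2 higher and 1 lower in DMSO and 3 and 3 in AMD3100). Inflammatory cytokines had 1 of 11 higher and 0 lower in each injury comparison (in DMSO 2 and 0 adjusted over the list alone, median 0.64, adjusted p = 0.220; in AMD3100 2 and 1, median 0.23, adjusted p = 0.618). Circadian clock genes had 2 of 19 higher and 2 lower in DMSO (2 and 3 adjusted over the list alone; adjusted p = 0.542) and 1 and 1 in AMD3100 (1 and 1 adjusted over the list alone; adjusted p = 0.251; 0.0455 by fry, which passed in 1 of 12 fits with 1 library left out, that without uninjured AMD3100 replicate 1).

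Other splits of the same libraries were counted for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Each other split mixes libraries of both real groups, so a real difference widens the spread within its groups and lowers its count. For injury in DMSO, 1 of the 10 splits, the real one, gave as many as 439 genes, and the highest of the others gave 1. For injury in AMD3100, 1 of 10 gave as many as 458, and the highest other gave 27. For AMD3100 in injured larvae all 10 splits gave the real count of 0 and the highest other was 0, which any split reaches. For AMD3100 in uninjured larvae 2 of 10 gave the real count of 1, with 1 as the highest other. For the interaction, all 100 of 100 splits reach the real count of 0, and the highest other gave 2, so this count says nothing about chance.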
